A study of Mus musculus with 10 samples.

How the data were processed

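Total RNA of left kidneys of C57BL/6 mice, 5 sham-operated and 5 UUO samples, was sequenced after stranded library preparation on a NovaSeq instrument, 1 library per sample. Per the submitters' processing notes the tools were cutadapt, HISAT2 and StringTie and the build GRCm38. Tool versions and the annotation release are not given in the sources used here. The authors deposited values of genes and of transcripts, whose header names no unit, and their values were taken as FPKM from the decimals, from equal gene and transcript values where a gene has 1 listed transcript, and from the column sums. FPKM and TPM would differ by 1 factor per library, a change covered by the rescaling described here. The threshold for listing a gene is not given in the sources used here, and only protein-coding genes were listed: 13920 genes and 26686 transcripts. From each file 1 empty line was not analysed here, and 14 gene symbols were shared by more than 1 gene and were skipped when genes were named. Every column of values was matched to its sample by the code in the sample titles, and groups followed the titles. Time after obstruction and sex are not given in the labels.

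Values were analysed as log2(FPKM + 1) in R 4.3.3, with figures and depth estimates in Python 3.11.15 (numpy 2.4.6, pandas 2.3.3, matplotlib 3.10.9). Genes and transcripts with at least 0.5 FPKM in at least 5 libraries were tested, which left 13202 genes and 21412 transcripts, and 718 genes were not tested. A gene below 0.5 FPKM in all 5 sham libraries was thus tested only if all 5 UUO libraries reached it. For such a gene the filter fixed the direction, and the same holds with the groups exchanged. UUO was compared with sham in limma 3.58.1 (lmFit, eBayes with a trend), with Benjamini-Hochberg adjustment and calls at an adjusted p below 0.05. Doubled and halved genes were called genes with a log2 difference of at least 1 in size. Because 1 is added before the logarithm, such differences understate the change of genes with low values, and folds in the text are ratios of mean FPKM. For 10 marker genes an exact two-sided permutation test of the difference of means was run over all 252 relabellings. Transcript shares, each transcript's part of its gene's sum, were compared in limma after an arcsine square-root transformation. That test took genes with at least 2 listed transcripts and a sum of at least 1 FPKM in every library, and transcripts with a mean share of at least 5% in either group, and called a difference of at least 10 percentage points.

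Gene lists, 42 in number, were fixed before the data were examined, as were the comparisons, thresholds and alternatives, and 39 had the 3 tested members needed. They were tested with limma's camera at a preset correlation of 0.01 between genes, with adjustment over the lists. Camera compares the moderated t-statistics of a list's genes (differences over their errors) with those of all other genes tested. Its direction can therefore differ from that of the mean log2 difference. Some lists share genes, such as collagens with the matrix list and keratins with the injury list, so their results are not independent. With an estimated correlation 0 lists were called by camera, 6 had an unadjusted p under 0.05, and fry, which tests a list without reference to other genes, called 25 higher and 12 lower. Counts adjusted over the list alone differed from those adjusted over all genes for 5 lists: thick ascending limb (8 lower), urothelium (9 higher), red blood cell (1 lower), solute carriers (82 higher, 130 lower) and cytosolic ribosomal proteins (79 higher). Sign differed between measures for 5 lists: nephron development had a median and mean above 0 and camera below 0, glycolysis a median below and a mean above 0, histones a median above 0 and camera below 0. Cytochrome P450 genes were placed lower by camera and higher by fry, and endothelial markers had a median, mean, camera and fry above 0 and camera on ranks below 0.

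Genes named in the text followed a fixed rule. It took the 10 markers, and the 8 called genes with the largest rise and the 8 with the largest fall among those with a symbol, non-overlapping groups and a mean of at least 5 FPKM in the higher group. From each list it took the called member with the largest change, the called member with the highest mean over all libraries, and, where members were called both ways, the one with the largest change in the rarer direction. Where no member was called it took the tested member with the highest mean. It further took the 5 called transcripts with the largest share difference whose gene averaged at least 5 FPKM, counting a pair from 1 gene once. Of the genes it gave, 91 are named or counted among the named genes, and some results are not reported here. Gene families by symbol root, and single genes described as such, were chosen after values were seen. A planned comparison with the authors' own calls was not made, since the tables used here hold no columns of such calls.

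Depth is not given in the sources used here. Multiplying FPKM by transcript length (GENCODE M21 lengths, which matched 25343 of the 26686 transcripts by identifier and version) gave 1 recurring low value in each of the 5 sham libraries, at 70.9 to 89.7 (39 to 60 values within 0.4%). The UUO libraries had no clear recurring value (at most 16). Whether evenly spaced multiples of it followed was not tested. The depth of the groups could therefore not be compared, and a value of 0 is reported as listed at 0. The tests were tried on simulated data of the same size, with each gene's spread within groups and changed genes drawn from those with a mean log2 value above 2. Of genes changed by a log2 difference of 0.5, 1 and 2, 41.8%, 88.1% and 93.9% were called, with 3 of 13002 unchanged genes called. Both changed lists and 0 of 37 others were called, as were 57.5% of transcripts changed by 1 (and 4 of 21212 unchanged) and 174 of 200 changed shares (and 11 of 13967 unchanged). Simulated genes varied independently of each other, whereas the estimated correlation within lists reached 0.94 (neutrophil markers). The simulation therefore does not show how often lists of correlated genes are called without a change. Alternatives were pseudocounts of 0.1 and 0.01, no filter, a filter at 1 FPKM, rescaling to equal sums of 1e+06, median-of-ratios and quantile scaling, robust eBayes, sample weights, an exact rank-sum test, the replicate number as a block, an estimated correlation, fry and camera on ranks for the lists, a gene sum of 5 FPKM, a share difference of 20 points and untransformed shares, and leaving out each library in turn, to which leaving it out with the tested genes kept was added after the data were seen. Other splits of the 10 libraries were drawn as 100 of the 126 possible. A library was set apart from the other 4 of its group by Dixon's ratio at the 95% critical value of 0.71.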

Results

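RNA was measured in left kidneys of C57BL/6 mice that had undergone either unilateral ureteral obstruction (UUO), the tying off of 1 ureter that makes the kidney above it swell and scar, or a sham operation. Each group had 5 libraries, made from total RNA of the whole organ with a stranded kit, and the comparison asked which genes differed between obstructed and sham-operated kidneys. The values of 13920 protein-coding genes and 26686 of their transcripts were taken as FPKM, fragments scaled by transcript length and library size. The sum of the gene values lay between 327994 and 343018 in sham and between 282172 and 302519 in UUO libraries. Between 276 and 357 genes were listed at 0 in a sham library and between 42 and 61 in a UUO library. No read counts were given, so the depth is unknown except through a recurring low value of FPKM times transcript length, which appeared in the 5 sham libraries alone. That value differed by 1.26-fold between the highest and the lowest sham library. Nothing in the labels says that the libraries came from separate animals, so p-values measure the spread between these samples.

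The Y-linked gene Ddx3y stood at 11.1 FPKM or higher in all 10 libraries. The first principal component of the log2 values of 13202 genes held 83.0% of the variance and placed the 5 sham libraries on one side and the 5 UUO libraries on the other. The second component held 4.58% and parted Sham 4 from the other sham libraries. Pearson correlations across genes, which are not independent replicates, ran from 0.989 to 0.992 between sham libraries other than Sham 4. Sham 4 correlated with them at 0.965 to 0.974, UUO libraries with each other at 0.946 to 0.977, and sham with UUO libraries at 0.783 to 0.885. Genes of the mitochondrial genome made up 21.2% to 24.5% of the FPKM sum in sham and 9.31% to 13.4% in UUO libraries.

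**Figure D1:**
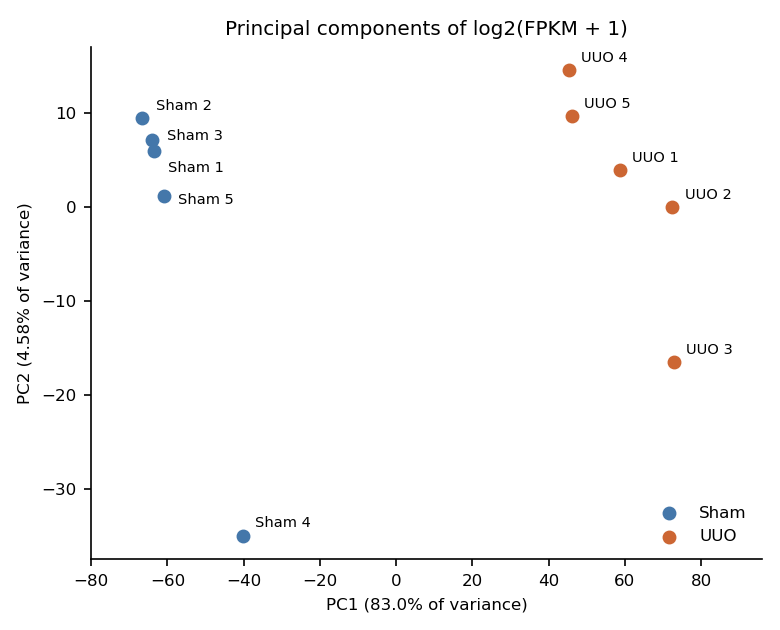
Principal components 1 and 2 of the log2(FPKM + 1) values of the tested genes, with 1 point per library. Component 1 (83.0% of the variance) separates the groups, and Sham 4 lies apart from the other sham libraries on component 2 (4.58%).

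Marker genes fixed in advance checked the labels, since obstruction was the only treatment. Havcr1, which encodes the tubular injury molecule KIM-1, rose from 0.556 ± 0.119 FPKM in sham to 301 ± 133 in UUO (mean ± SD, n = 5 each), a log2 difference of 7.51 with a standard error of 0.23 (limma, adjusted p = 1.94e-08). Lcn2, the secreted injury marker lipocalin 2, rose from 1.16 ± 1.03 to 196 ± 141 FPKM, with a sham mean of 0.706 without Sham 4. The matrix genes Col1a1 and Fn1 rose from 1.39 ± 0.169 to 128 ± 51.7 and from 0.798 ± 0.160 to 30.8 ± 7.09 FPKM, and Acta2, the smooth muscle actin of myofibroblasts, rose 9.72-fold to 76.8 ± 22.9. The macrophage marker Adgre1 (F4/80) rose from 0.388 ± 0.127 to 16.97 ± 8.64 FPKM. Slc34a1, the phosphate transporter of the proximal tubule, fell from 792 ± 126 to 265 ± 169 FPKM, and the anti-ageing gene Kl fell from 80.9 ± 12.1 to 18.6 ± 6.73. Aqp2, the water channel of the collecting duct, fell from 141 ± 145 to 17.5 ± 10.8 FPKM, where Sham 4 stood at 399 and the other sham libraries between 62.1 and 90.6 (mean 76.4). In these 9 genes no sham library overlapped a UUO library, which gave the exact two-sided permutation test its smallest possible p of 0.00794. Umod, the thick ascending limb's uromodulin, did not pass: it averaged 661 ± 133 FPKM in sham and 444 ± 212 in UUO (limma, adjusted p = 0.0538; exact permutation p = 0.103), with UUO 1 and UUO 3 at 681 and 670.5. With median-of-ratios scaling its log2 difference was -1.19 (limma, adjusted p = 0.00323), and without UUO 1 or UUO 3 it was -0.87 or -0.86 (limma, adjusted p = 0.0162 and 0.0166). In GRCm38 coordinates the genes span chromosome 11 from 46735080 to 46779578 (Havcr1), chromosome 2 from 32384633 to 32388252 (Lcn2) and chromosome 11 from 94936224 to 94953042 (Col1a1). Slc34a1 spans chromosome 13 from 55398187 to 55415592 and Aqp2 chromosome 15 from 99579056 to 99584545.

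**Figure D2:**
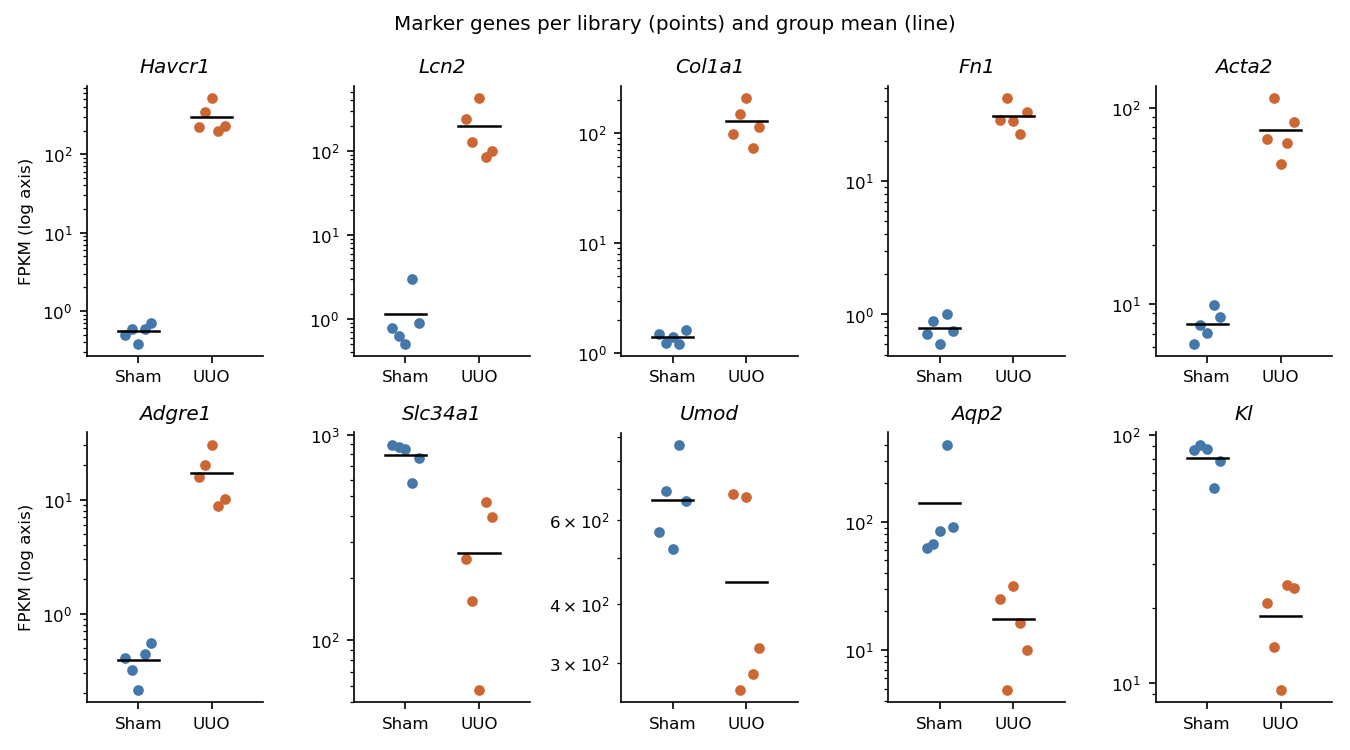
FPKM of the 10 marker genes on a log axis, with 1 point per library, sham beside UUO, and a line at each group's mean. The groups do not overlap in any gene except Umod, and Havcr1 shows the widest separation, from 0.556 in sham to 301 in UUO.

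Complement C3 rose from 1.77 ± 2.23 to 272 ± 141 FPKM (n = 5 each), where Sham 4 stood at 5.75 and the other sham libraries at or below 0.996 (mean 0.778). Lyz2, the lysozyme of macrophages, rose from 8.31 ± 2.71 to 568 ± 173 FPKM, and how reads shared with its close relative Lyz1 were divided is unknown. Timp1, an inhibitor of matrix metalloproteinases, rose from 0.0656 ± 0.104 FPKM in sham to 102 ± 99.9 in UUO, with a UUO mean of 58.7 without UUO 3 and a sham mean of 0.0223 without Sham 1. Sprr2f, of a family of near-identical small proline-rich genes, and the metalloproteinase gene Mmp7 were listed at 0 in all 5 sham libraries and stood, from UUO 1 to UUO 5, at 39.9, 38.4, 101, 45.4 and 29.3 and at 77.1, 38.9, 159, 18.4 and 19.5 FPKM. Slc22a7, an organic anion transporter, fell 22.5-fold from 147 ± 28.5 to 6.53 ± 6.37 FPKM (34.7-fold without UUO 4), and Egf, the epidermal growth factor of the distal nephron, fell 25.9-fold from 101 ± 18.2 to 3.92 ± 2.97. Slco1a1, the amino acid transporter gene Slc7a13, the acyl-CoA synthetase gene Acsm3 and the brush-border protease gene Mep1b fell 13.9, 11.7, 13.7 and 12.3-fold. Nccrp1 and the glutathione peroxidase gene Gpx6 fell 35.6 and 20.7-fold, the latter 37.3-fold without UUO 1. Of 13202 genes tested, 7727 were higher and 2130 lower in UUO (limma on log2(FPKM + 1), Benjamini-Hochberg adjusted p below 0.05), and 2472 at least doubled while 690 at least halved. At least doubled and halved were 1530 and 1346 with median-of-ratios scaling, 1317 and 1097 under quantile normalization and 4235 and 586 after rescaling to equal sums. They were 3764 and 799 with a pseudocount of 0.1 and 3896 and 815 with 0.01. In FPKM as deposited the sham and UUO values did not overlap in 7879 of the 13202 tested genes (59.7%), of which 7858 were called. Chance gives such a separation in 0.794% of genes. The median-of-ratios scaling factors did not overlap either, at 0.79 to 0.94 in sham and 1.14 to 1.24 in UUO libraries. A difference in scale between the groups can thus separate genes as well, and the count was not made under other scalings. The median gene lay 0.40 higher in UUO on the log2 scale, a shift that median-of-ratios scaling moved to 0.002. The split of calls then became 4506 higher and 4522 lower, with 6636 of the 9857 kept in their direction and 301 called the opposite way. Quantile normalization gave 3908 higher and 4825 lower. Log2 differences on the log2(FPKM + 1) scale understate the change of genes with low values. Genes below 0.5 FPKM in every sham library, such as Timp1 and Mmp7, were tested only because all 5 UUO libraries reached it. That fixed their direction, and the counts of higher genes in the lists include such genes.

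Genes of the extracellular matrix rose as a group: 25 of 25 tested were higher in UUO and 0 were lower, with a median log2 difference of 3.25 (limma's camera, adjusted p = 4.32e-08; adjusted p = 0.239 with an estimated correlation). Sparc, a collagen-binding glycoprotein, rose 13.1-fold from 19.1 ± 3.99 to 251 ± 54.1 FPKM (n = 5 each), beside the rises of Col1a1, Fn1 and Timp1. All 14 tested markers of fibroblasts, myofibroblasts and pericytes were higher, with a median of 2.21 (limma camera, adjusted p = 0.000463; adjusted p = 0.246 with an estimated correlation). Tagln, an actin-binding protein of smooth muscle, rose 12.4-fold from 7.63 ± 1.55 FPKM and the surface glycoprotein gene Thy1 from 0.345 ± 0.109 to 20.3 ± 6.97. In the collagen family 21 of 25 genes rose and 2 fell (limma camera, adjusted p = 0.000589; adjusted p = 0.246 with an estimated correlation). Col4a3, a chain of the glomerular basement membrane, fell from 22.9 ± 1.85 to 13.7 ± 2.65 FPKM. All 11 tested matrix metalloproteinase genes rose (limma camera, adjusted p = 0.000781, and adjusted p = 0.239 with an estimated correlation). Mmp7, listed at 0 in every sham library, was tested only because all 5 UUO libraries reached the filter, which fixed its direction. Of the ADAMTS proteases 13 of 14 rose, Adamts1 from 6.92 ± 1.44 to 64.8 ± 19.6 FPKM (limma camera, adjusted p = 0.00121; adjusted p = 0.239 with an estimated correlation). Of the TGF-beta and BMP genes 15 of 17 were higher and 1 lower (limma camera, adjusted p = 0.0178; adjusted p = 0.351 with an estimated correlation). The activin subunit gene Inhba rose from 0.0542 ± 0.0351 to 8.17 ± 3.54 FPKM and the receptor gene Tgfbr2 from 10.7 ± 1.41 to 24.3 ± 4.38, while Bmp7, a growth factor that opposes TGF-beta in the kidney, fell from 10.7 ± 0.949 to 6.52 ± 1.26. The call of the TGF-beta list ended when any 1 UUO library was left out (limma camera, adjusted p between 0.104 and 0.123), where members below the filter in every sham library, such as Inhba, were no longer tested. With the tested genes kept, a test added afterwards, it held without each UUO library (limma camera, adjusted p between 0.0148 and 0.0200). That set keeps genes such as Inhba, which passed the filter through their UUO values, so it is no independent support.

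Most immune cell markers rose. All 15 tested macrophage and monocyte genes were higher, with a median log2 difference of 3.25 (limma's camera, adjusted p = 1.32e-05; adjusted p = 0.239 with an estimated correlation). All 9 tested T and NK cell genes rose, Lck from 0.225 ± 0.122 to 2.94 ± 1.36 FPKM and Nkg7 from 0.341 ± 0.289 to 3.09 ± 1.07 (n = 5 each), and 5 did under quantile normalization. That list passed the test (limma camera, adjusted p = 0.0283; adjusted p = 0.369 with an estimated correlation) but not without Sham 4 (limma camera, adjusted p = 0.0664) or with the filter at 1 FPKM (limma camera, adjusted p = 0.0990). Without any 1 of the UUO libraries members such as Lck fell below the filter and the call ended (limma camera, adjusted p between 0.123 and 0.199), and with the tested genes kept, a test added afterwards, it held (between 0.0131 and 0.0358). Genes such as Lck were tested only because all 5 UUO libraries reached the filter, which fixed their direction. Keeping the tested genes keeps that selection, so it is no independent support. Of the 13 T and NK, 9 B and plasma and 10 neutrophil genes fixed in advance, 9, 3 and 4 were tested. Whichever UUO library was left out, too few B cell and neutrophil genes passed the filter for either list to be tested. Some of those genes thus passed through their UUO values, and their rise is no independent support. In the B and plasma cell list 2 of 3 tested genes rose, Cd79b from 0.580 ± 0.435 to 2.86 ± 0.646 FPKM, against 1 higher and 1 lower under quantile normalization. All 4 tested neutrophil genes rose, S100a9 from 0.550 ± 0.233 to 60.2 ± 91.8 FPKM, a log2 difference of 4.32 that was 3.60 without UUO 3 (UUO mean 19.2). Neither the B cell list nor the neutrophil list passed as a group (limma camera, adjusted p = 0.619 and 0.182). The neutrophil list did with median-of-ratios and quantile scaling (limma camera, adjusted p = 0.0307 and 0.0395), though not with median-of-ratios scaling and an estimated correlation (limma camera, adjusted p = 0.343). Of the chemokines and cytokines 18 of 19 were higher (limma camera, adjusted p = 0.000209; adjusted p = 0.239 with an estimated correlation). The monocyte attractant gene Ccl2 rose from 0.127 ± 0.138 (0.0761 without Sham 3) to 40.4 ± 15.3 FPKM and Cxcl16 6.81-fold to 64.1 ± 9.90. Among complement genes 10 of 13 rose and 1 fell (limma camera, adjusted p = 0.0249; adjusted p = 0.351 with an estimated correlation). Cd55, which shields cells from complement, fell from 5.33 ± 0.414 to 3.61 ± 0.714 FPKM. All 15 interferon response genes rose, Gbp2 from 4.45 ± 1.88 to 62.6 ± 31.8 FPKM (limma camera for the list, adjusted p = 0.00622; adjusted p = 0.447 with an estimated correlation).

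All 18 tubular injury markers rose, with a median log2 difference of 3.51 (limma's camera, adjusted p = 2.26e-05; adjusted p = 0.246 with an estimated correlation). Spp1, which encodes the secreted phosphoprotein osteopontin, rose 22.4-fold from 275 ± 56.3 to 6159 ± 2108 FPKM (n = 5 each). In the keratin family 10 of 12 genes rose, Krt20 from 0.275 ± 0.502 (0.0533 without Sham 4) to 37.3 ± 15.4 FPKM and Krt8 from 61.7 ± 5.52 to 211 ± 22.2. The 1 that fell, Krt10, fell by 0.24 on the log2 scale, a call that was lost when values were rescaled to equal sums (log2 difference -0.10; limma, adjusted p = 0.423). It was also lost without Sham 1, 2 or 3 or UUO 1, 2 or 3 (limma, adjusted p from 0.0539 to 0.0883). The keratin list narrowly missed the threshold (limma camera, adjusted p = 0.0541) and passed it without Sham 4 or UUO 1 (limma camera, adjusted p = 0.0169 and 0.0478) and with median-of-ratios and quantile scaling (adjusted p = 0.00260 and 0.00104). With median-of-ratios scaling and an estimated correlation it did not pass (limma camera, adjusted p = 0.254). Among claudins, which seal the junctions between epithelial cells, 8 of 14 rose and 1 fell, Cldn4 from 9.51 ± 8.05 (5.91 without Sham 4) to 97.2 ± 15.6 FPKM and Cldn10 from 69.1 ± 9.11 to 37.8 ± 8.28 (limma camera for the family, adjusted p = 0.313, or 0.0122 under quantile normalization). Proliferation genes were higher in 15 of 15 cases, the cyclin gene Ccnb2 14.5-fold to 7.23 ± 2.16 FPKM and the replication clamp gene Pcna from 14.8 ± 1.86 to 31.2 ± 4.47 (limma camera, adjusted p = 0.000204; adjusted p = 0.255 with an estimated correlation). Of the arrest and senescence genes 9 rose and 3 of 12 fell (limma camera, adjusted p = 0.443, or 0.0182 under quantile normalization). The kinase inhibitor gene Cdkn1a (p21) rose 20.7-fold from 1.19 ± 0.328 to 24.6 ± 3.06 FPKM, while the binding protein gene Igfbp5 fell from 78.8 ± 34.8 to 41.7 ± 7.83. Glb1, the gene of the lysosomal galactosidase used to stain senescent cells, fell from 75.9 ± 8.55 to 37.1 ± 7.05 FPKM. Genes of regulated cell death rose in 13 of 16 cases and fell in 1 (limma camera, adjusted p = 0.0132; adjusted p = 0.246 with an estimated correlation). Gsdmd, which forms the pore of pyroptosis, rose 19.3-fold to 18.98 ± 3.34 FPKM, and Gpx4, which protects membranes from lipid peroxidation, fell from 352 ± 30.2 to 269 ± 28.5, a call lost when values were rescaled to equal sums (limma, adjusted p = 0.0571).

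Most markers of the tubule segments fell. All 20 proximal tubule markers were lower, with a median log2 difference of -1.67 (limma's camera, adjusted p = 4.84e-12; adjusted p = 0.239 with an estimated correlation). Kap, a protein of the proximal tubule under androgen control, fell 3.33-fold from 20977 ± 3222 to 6299 ± 3497 FPKM (n = 5 each), though not under quantile normalization (limma, adjusted p = 0.157). In the thick ascending limb list 7 of 10 genes fell and 1 rose (limma camera, adjusted p = 7.29e-05; adjusted p = 0.239 with an estimated correlation). Slc12a1, the cotransporter that loop diuretics block, fell from 213 ± 95.6 to 52.3 ± 13.4 FPKM, and Cldn16 rose from 6.74 ± 0.995 to 13.1 ± 4.46, a rise not called under median-of-ratios scaling (limma, adjusted p = 0.0957). Distal convoluted and connecting tubule markers fell in 8 of 10 cases and rose in 2 (limma camera, adjusted p = 3.65e-05; adjusted p = 0.239 with an estimated correlation). The calcium-binding protein gene Calb1 fell 14.5-fold from 75.5 ± 24.9 to 5.197 ± 3.17 FPKM and the kallikrein gene Klk1 from 1041 ± 281 to 195 ± 73.9, while Trpv5, a calcium channel gene, rose from 3.60 ± 1.03 to 8.95 ± 4.23, again not called under median-of-ratios scaling (limma, adjusted p = 0.0605). Principal cell markers fell in 6 of 10 cases and rose in 1, Gata3 (limma camera, adjusted p = 0.000508; adjusted p = 0.239 with an estimated correlation and 0.0548 under quantile normalization). The mean of that list was 4.98 log2 units in Sham 4 and 4.03 to 4.17 in the other sham libraries. Gata3 averaged 5.27 ± 3.08 FPKM in sham, of which Sham 4 stood at 10.8, and 10.1 ± 3.18 in UUO, and its call ended under median-of-ratios scaling (limma, adjusted p = 0.166). Of the intercalated cell markers 6 of 10 fell and 0 rose (limma camera, adjusted p = 2.49e-05; adjusted p = 0.239 with an estimated correlation). With median-of-ratios scaling 10 fell, under quantile normalization 8 and after rescaling to equal sums 4. The anion exchanger gene Slc4a1 dropped 11.8-fold to 0.612 ± 0.253 FPKM and the proton pump subunit gene Atp6v1g3 fell from 24.8 ± 4.59 to 16.7 ± 4.76, the latter call being lost when values were rescaled to equal sums (limma, adjusted p = 0.0626). Solute carriers changed both ways, with 129 of 275 genes lower and 81 higher (limma camera, adjusted p = 1.32e-11; adjusted p = 0.129 with an estimated correlation). With median-of-ratios scaling 169 solute carriers were lower and 56 higher, and under quantile normalization 181 and 37. The fatty acid carrier gene Slc27a2 fell from 1155 ± 115 to 460.0 ± 196 FPKM and the mitochondrial carrier gene Slc25a24 rose 19.1-fold to 26.6 ± 4.26 (30.4-fold without Sham 4). Cytochrome P450 genes were lower in 18 of 40 cases and higher in 12 (limma camera, adjusted p = 0.000285; adjusted p = 0.239 with an estimated correlation and 0.0922 under quantile normalization). By limma's fry the list was not called (adjusted p = 0.749). Cyp4b1 fell from 1184 ± 197 to 181 ± 123 FPKM, Cyp4a12a, one of several close copies, fell 9.77-fold, and Cyp1b1 rose 12.3-fold.

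Genes of oxidative metabolism fell. All 16 genes of fatty acid oxidation were lower (limma's camera, adjusted p = 1.50e-11; adjusted p = 0.239 with an estimated correlation). Ehhadh, a peroxisomal enzyme, fell from 287 ± 44.9 to 51.5 ± 33.0 FPKM and the dehydrogenase gene Acadm from 341 ± 39.7 to 79.1 ± 27.1 (n = 5 each). All 20 genes of oxidative phosphorylation and the TCA cycle fell (limma camera, adjusted p = 2.88e-16; adjusted p = 0.239 with an estimated correlation). The ATP synthase gene Atp5b fell from 513 ± 15.1 to 209 ± 32.9 FPKM. The 13 genes of the mitochondrial genome were all lower (limma camera, adjusted p = 1.11e-10; adjusted p = 0.239 with an estimated correlation), and 7 were under quantile normalization, where the list's call was lost (limma camera, adjusted p = 0.150). mt-Co1 fell from 10286 ± 367 to 5851 ± 793 FPKM, and quantile normalization gave it a log2 difference of 0.12 that did not pass. mt-Atp6, which overlaps mt-Atp8, stood at 6810 FPKM in Sham 4 and between 1145 and 1418 in the other sham libraries, against 595 ± 106 in UUO. All 8 gluconeogenesis genes fell, the phosphatase gene G6pc from 137 ± 40.8 to 29.6 ± 23.3 FPKM (limma camera, adjusted p = 9.17e-06; adjusted p = 0.239 with an estimated correlation). Glycolysis genes went both ways, 5 of 14 lower and 3 higher. Their median log2 difference was -0.18, their mean 0.01, and limma's camera called the list lower (adjusted p = 0.00235; adjusted p = 0.239 with an estimated correlation), while rescaling to equal sums turned the median to 0.02. With median-of-ratios scaling 9 were lower and 2 higher (median -0.68), and under quantile normalization the list's call was lost (limma camera, adjusted p = 0.365). Pgk1 fell from 212 ± 10.4 to 119.8 ± 10.4 FPKM, and the hexokinase gene Hk2 rose from 0.922 ± 1.86 to 5.72 ± 2.37, with Sham 4 at 4.25 and the other sham libraries at or below 0.189 (mean 0.0909). Among renin-angiotensin and endocrine genes 3 of 9 fell (5 with median-of-ratios scaling) and 1, the vitamin D hydroxylase gene Cyp27b1, rose from 0.593 ± 0.336 to 7.43 ± 1.63 FPKM. That list had a median of -0.10 and was called lower (limma camera, adjusted p = 0.0183; adjusted p = 0.246 with an estimated correlation), and its median became 0.09 after rescaling to equal sums. Its call ended with median-of-ratios scaling (limma camera, adjusted p = 0.107), under quantile normalization (limma camera, adjusted p = 0.365) and by fry (limma, adjusted p = 0.169).

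Podocyte markers rose in all 10 cases, among them Podxl, a sialoprotein of their foot processes, from 17.8 ± 2.07 to 31.1 ± 6.03 FPKM (n = 5 each), but median-of-ratios scaling left 5 higher and quantile normalization 4 higher and 2 lower. Podxl was not called with median-of-ratios scaling (limma, adjusted p = 0.0655). Of the endothelial markers 7 of 11 rose and 0 fell, against 4 and 2 with median-of-ratios scaling, 6 and 2 under quantile normalization and 10 and 0 without Sham 4. Cdh5, the cadherin of vessels, rose from 5.02 ± 2.79 to 13.8 ± 2.68 FPKM, with Sham 4 at 9.95 and the other sham libraries between 3.37 and 4.43. Plvap, at 45.7 ± 29.5 and 73.5 ± 14.5 FPKM with Sham 4 at 98.0, lost its call without Sham 1, 2, 3 or 5 or UUO 1 or 2 (limma, adjusted p from 0.0543 to 0.0721) and with median-of-ratios scaling (log2 difference 0.32; limma, adjusted p = 0.311). Neither list passed as a group (limma's camera, adjusted p = 0.117 and 0.559). The podocyte list did with median-of-ratios scaling (limma camera, adjusted p = 0.0410; adjusted p = 0.342 with an estimated correlation). Nephron development genes rose in 4 of 11 cases and fell in 1 (limma camera, adjusted p = 0.622), against 8 and 2 without Sham 4, and their median of 0.42 became -0.04 with median-of-ratios scaling. Wnt4 rose from 1.18 ± 2.12 to 7.29 ± 2.17 FPKM, with Sham 4 at 4.98 and the other sham libraries at or below 0.364 (mean 0.234), and Lhx1 fell from 5.27 ± 0.430 to 2.63 ± 0.332, while the regulator gene Sall1 was called higher at 0.37. Sall1 had -0.10 with median-of-ratios scaling (limma, adjusted p = 0.457). It lost its call without Sham 1, 2, 3 or 5 or UUO 2, 3 or 5 (limma, adjusted p from 0.0537 to 0.0756), and without UUO 1 when the filter was applied again (limma, adjusted p = 0.0511). Cytosolic ribosomal protein genes were higher in 78 of 81 cases and lower in 1, Rpl3l, a form typical of muscle (limma camera, adjusted p = 8.47e-09; adjusted p = 0.381 with an estimated correlation), against 63 and 2 with median-of-ratios scaling. Rplp1 stood at 479 ± 16.2 FPKM in sham and 996 ± 178 in UUO, and Rpl12 at 49.1 ± 3.67 and 153 ± 28.3. Histone genes, which share near-identical copies, were higher in 14 and lower in 13 of 34 cases (limma camera, adjusted p = 0.0809), with a median of 0.13 that became -0.14 with median-of-ratios scaling and -0.36 under quantile normalization. Hist1h2ap rose from 0.462 ± 0.137 to 8.81 ± 2.64 FPKM, and Hist1h2bc and Hist2h2aa2 fell from 154 ± 23.4 to 92.4 ± 16.4 and from 62.9 ± 4.45 to 24.8 ± 5.54.

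**Figure D3:**
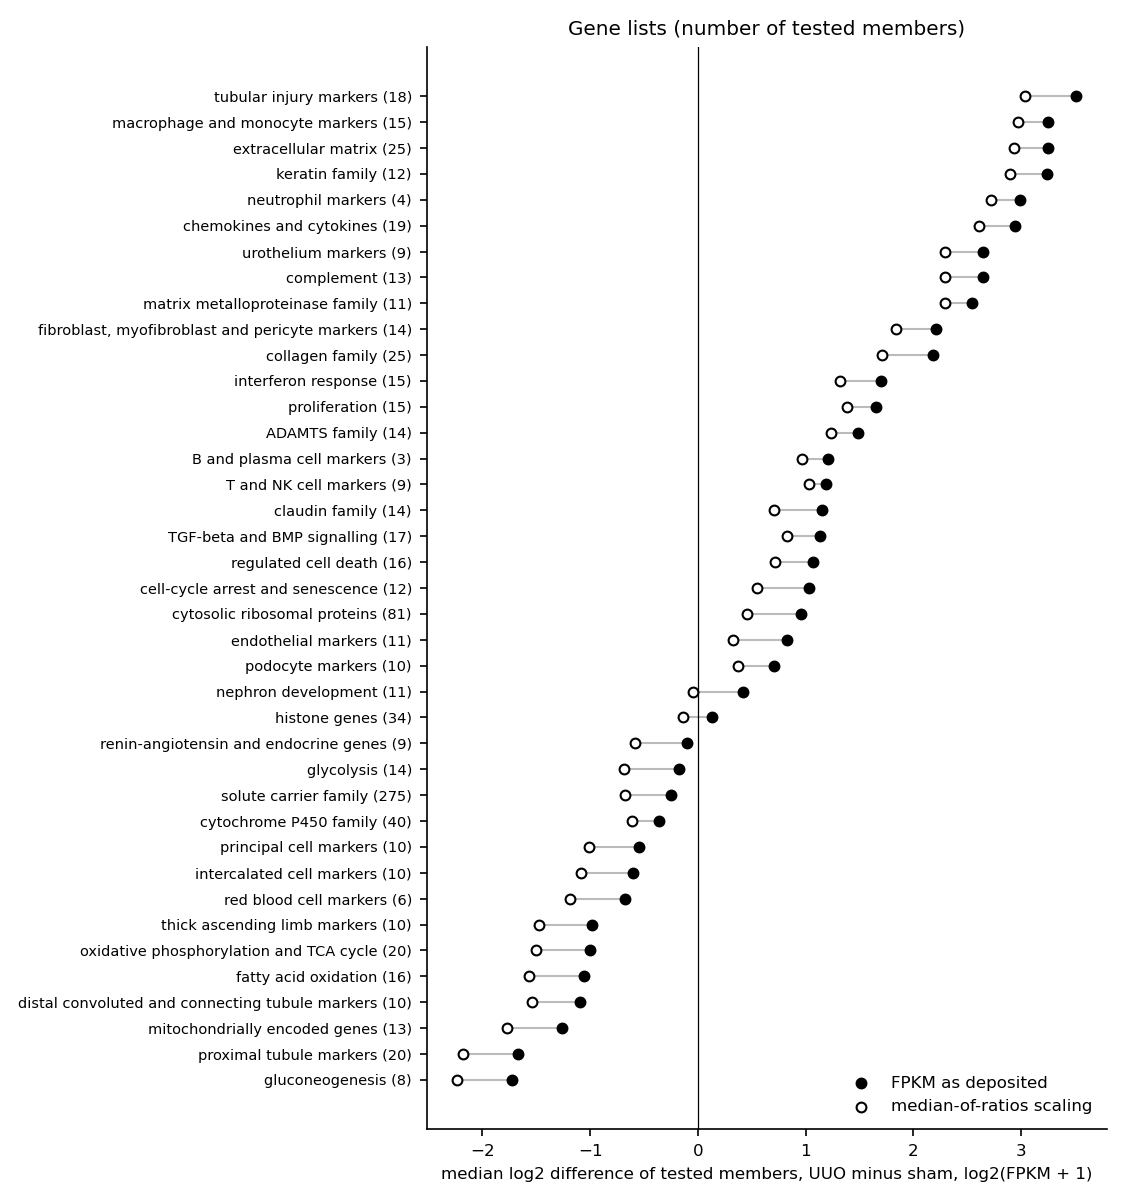
Median log2 difference (UUO minus sham) of each of the 39 gene lists tested, with filled points for FPKM as deposited and open points for median-of-ratios scaling. Extracellular matrix (3.25), macrophage (3.25) and tubular injury (3.51) lists lie highest and proximal tubule (-1.67) and gluconeogenesis (-1.72) lists lowest, and the medians of nephron development and histone genes change sign with the scaling.

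Markers of tissue next to the kidney were read as a check of what each sample held. Urothelial genes rose in 8 of 9 cases, Krt14 from 0.124 ± 0.1002 to 37.1 ± 20.7 FPKM (n = 5 each), without passing as a group (limma's camera, adjusted p = 0.182). The list did pass with median-of-ratios and quantile scaling (limma camera, adjusted p = 0.0155 and 0.0143), though not with median-of-ratios scaling and an estimated correlation (limma camera, adjusted p = 0.403). It also passed by fry, which makes no comparison with other genes (limma, adjusted p = 0.00116). The urothelial and prostate antigen gene Psca stood at 93.7 FPKM in Sham 4, between 0.715 and 7.03 in the other sham libraries and between 15.6 and 103 in UUO, a log2 difference of 2.77 that was 3.73 without Sham 4. Its call (limma, adjusted p = 0.0230) ended without Sham 2, Sham 3 or UUO 4, with adjusted p between 0.0544 and 0.0577, and in the exact rank-sum test (adjusted p = 0.121). Of 7 listed adipocyte genes 2, Adipoq and Cfd, could be tested and neither passed, nor did either at an unadjusted p under 0.05 (limma). Cfd, the fat cell protease adipsin, stood at 124 FPKM in Sham 4, at or below 4.69 in the other sham libraries and between 0.137 and 64.4 in UUO (limma, adjusted p = 0.286, or 0.0303 without Sham 4). The adipokine gene Adipoq stood at 28.1 in Sham 4, at or below 0.903 in the other sham libraries and between 0.103 and 4.99 in UUO (limma, adjusted p = 0.841). Ucp1, the uncoupling protein of brown fat, named after its values were seen, stood at 92.5 FPKM in Sham 4, at or below 1.46 in the other sham libraries and at or below 0.108 in UUO. Neither of the 2 listed adrenal cortex genes reached the filter. Red blood cell genes fell in 3 of 6 cases (limma camera, adjusted p = 0.00121; adjusted p = 0.246 with an estimated correlation) and in 1 without Sham 4. With median-of-ratios scaling 6 fell and after rescaling to equal sums 1, and under quantile normalization the list's call was lost (limma camera, adjusted p = 0.102). Hba-a1, a copy nearly identical to Hba-a2, stood at 153 ± 62.1 FPKM in sham and 91.3 ± 28.9 in UUO and lost its call without Sham 1, Sham 4, UUO 3, UUO 4 or UUO 5 (limma, adjusted p between 0.0738 and 0.0853). Its call was also lost after rescaling to equal sums, under quantile normalization and with sample weights (limma, adjusted p = 0.117, 0.119 and 0.125). The exact rank-sum test did not call it either (adjusted p = 0.181). Of the 4 sex-linked genes 3 were called higher, and their median of 0.39 became -0.01 with median-of-ratios scaling and -0.11 under quantile normalization.

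**Figure D4:**
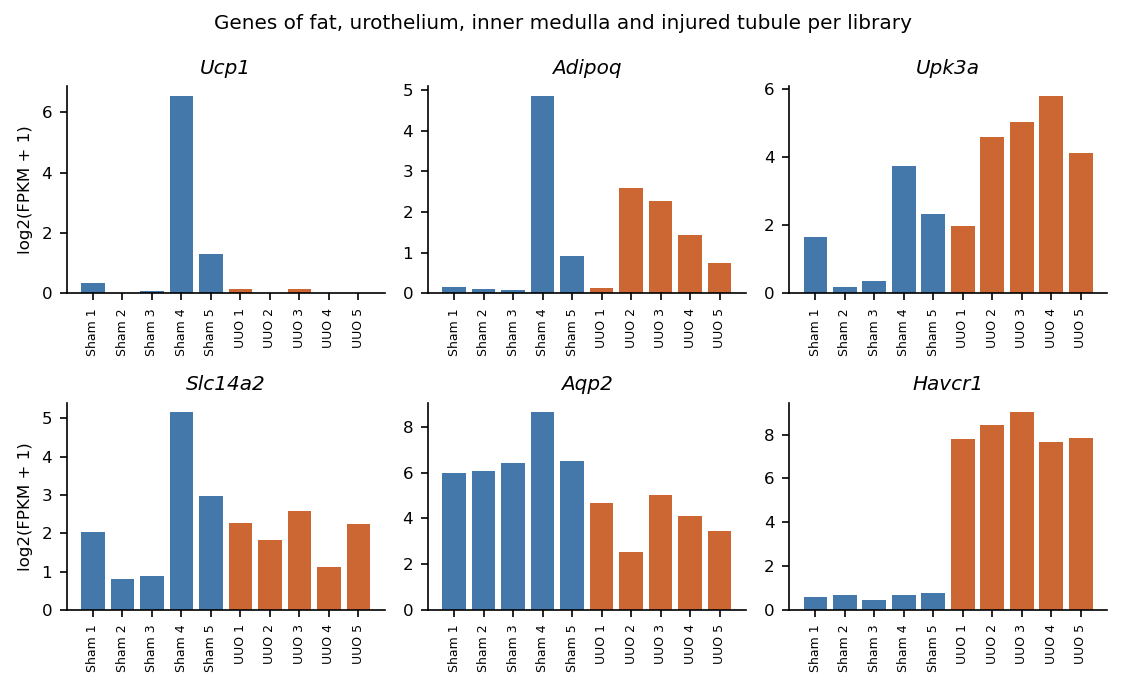
log2(FPKM + 1) of Ucp1, Adipoq, Upk3a, Slc14a2, Aqp2 and Havcr1 in each of the 10 libraries, as bars from 0. Sham 4 holds the highest sham value of the first 5 genes (Ucp1 at 92.5 FPKM, Aqp2 at 399), while its Havcr1 value of 0.594 FPKM lies among those of the other sham libraries.

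Transcripts of one gene can change their proportions without a change of the gene, so the share of each transcript in its gene's total was compared as well. In the listed values the guanylate cyclase subunit gene Gucy1a3 exchanged its leading transcript: ENSMUST00000048976.7 was listed at 0 in all 5 sham libraries and held 99.8% ± 0.393 of the gene in UUO (SD, n = 5), and ENSMUST00000193924.5 went from 100% in every sham library to 0.241% ± 0.393 (limma, adjusted p = 2.65e-09 for both). These transcripts lie on chromosome 3 of GRCm38, from 82092437 to 82145787 and from 82092427 to 82145073, and the gene's sum rose from 1.83 to 17.6 FPKM. Il33, which encodes an alarmin cytokine, did likewise on chromosome 19: the share of ENSMUST00000025724.8 (29945790 to 29960704) was 0 in 4 sham libraries, 25.0% in Sham 4 and 94.0% ± 1.76 in UUO, while ENSMUST00000120388.8 (29925114 to 29960718) dropped by 91.7 points to 3.35% ± 0.911 (limma, adjusted p = 0.000893 and 0.000646). The sum of Il33 rose from 1.60 to 22.9 FPKM. All shares rest on how the processing divided reads between overlapping transcripts of a gene. Whether low or differing coverage affected that division was not tested, so a switch of transcripts in the tissue is not shown. The Reps2 transcript ENSMUST00000112334.7 (chromosome X, 162411954 to 162643649) went from 0.568% ± 1.27 to 82.6% ± 38.5, with UUO 2 at 13.8%, and Nfya-201 (chromosome 17, 48386896 to 48409765) from 16.7% ± 36.8 to 95.6% ± 3.58, with Sham 3 at 82.5% (limma, adjusted p = 0.0299 and 0.0453). 2900026A02Rik-202 fell from 91.8% ± 18.1 to 14.7% ± 7.98 and 2900026A02Rik-203 rose from 8.22% ± 18.1 to 78.7% ± 21.5 (chromosome 5, from 113086323 to 113221236 and to 113137986; limma, adjusted p = 0.00903 and 0.0288). Of 14003 transcripts of 5525 genes, 105 in 73 genes changed their share by at least 10 percentage points, 46 to a larger and 59 to a smaller share in UUO. The gene as a whole was higher in 38 of the 73, lower in 19 and not called in 16, and the leading transcript differed between the groups in 42. Among 21412 transcripts tested by level, 6898 were higher and 2608 lower (limma, adjusted p below 0.05), and 4524 and 4346 with median-of-ratios scaling. Leaving out any 1 library ended the calls of ENSMUST00000112334.7 (save for UUO 2), Nfya-201 (save for Sham 3) and 2900026A02Rik-203 (save for Sham 5 and UUO 5), with adjusted p from 0.0527 to 0.101 (limma), and none of the calls of Gucy1a3, Il33 and 2900026A02Rik-202. With a gene sum of at least 5 FPKM required in every library, Nfya-201 kept its call and the other transcripts named here were not tested, their genes' sums being lower in at least 1 library.

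**Figure D5:**
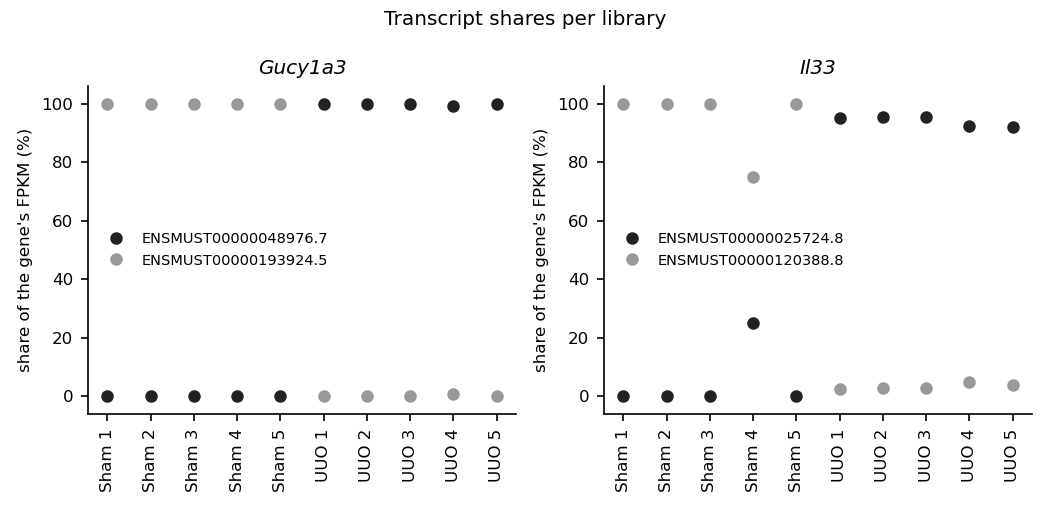
Share (%) of the Gucy1a3 and Il33 transcripts in their gene's FPKM sum in each library, sham beside UUO. ENSMUST00000048976.7 lies at 0 in all 5 sham libraries and near 100% in UUO, and ENSMUST00000025724.8 lies at 0 in 4 sham libraries, at 25.0% in Sham 4 and above 91% in UUO.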

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

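Both tests of why Sham 4 differed were chosen only after its values were seen. Among 278 groups of 5 values (named genes, list means and named transcript shares), 37 held 1 library apart from the other 4, of which 25 were Sham 4, and chance gives about 1 in 20 groups, or 13.9.

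In Sham 4, genes of fat, urothelium and collecting duct were high: Ucp1 of brown fat stood at 92.5 FPKM (other sham libraries at or below 1.46), Adipoq at 28.1 (at or below 0.903), Cfd at 124 (at or below 4.69), the urothelial Upk3a at 12.3 (0.143 to 3.97), the inner medullary urea transporter Slc14a2 at 34.7 (0.747 to 6.82) and the water channel Aqp4 at 38.6 (at or below 9.52). Of the 26 members of the urothelium, adipocyte and principal cell lists, 80.8% were highest in Sham 4 among sham libraries (8 of 9, 7 of 7 and 6 of 10, the last list being of kidney cells), against 50.2% of all tested genes. These lists were picked because such genes had been seen to be high, so this share restates what was seen and decides nothing, and whether tissue of the papilla, pelvis and hilar fat was in this sample stays open. RNA of an obstructed kidney mixed into the library is argued against as the whole cause. Of the 476 genes at least doubled in Sham 4, 59.7% (284) lay above the UUO mean of log2(FPKM + 1), which a mixture with a kidney at that mean cannot reach. A mixture with 1 kidney could pass that mean for some genes: Psca stood at 93.7 FPKM in Sham 4 and at 103 in UUO 4, with a mean FPKM of 52.9 in UUO. Havcr1 stood at 0.594 FPKM in Sham 4, between 0.384 and 0.702 in the other sham libraries and between 198 and 515 in UUO. Whether the sample, the dissection or the animal differed stays open, and no biological explanation was tested because the design gives none.

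Further genes were high in Sham 4 (FPKM, with the range of the other sham libraries): Lcn2 at 2.99 (0.510 to 0.905), Aqp2 at 399 (62.1 to 90.6), C3 at 5.75 (0.571 to 0.996), Lyz2 at 13.1 (6.52 to 7.56), Gata3 at 10.8 (3.77 to 3.98), Slc4a1 at 14.2 (4.75 to 6.33), Cdh5 at 9.95 (3.37 to 4.43) and Plvap at 98.0 (26.7 to 38.6). So were Igfbp5 at 141 (58.7 to 70.2), Wnt4 at 4.98 (0.143 to 0.364), Hk2 at 4.25 (0.0183 to 0.189), Krt20 at 1.16 (0 to 0.176), Cldn4 at 23.9 (5.39 to 6.36) and mt-Atp6 at 6810 (1145 to 1418). Slc27a2 was low at 959.7 (1144 to 1228). Among list means (log2), Sham 4 was high for principal cell (4.98 against 4.03 to 4.17), endothelial (3.63 against 2.69 to 2.91), macrophage (1.55 against 1.24 to 1.33), tubular injury (3.32 against 2.52 to 2.73), nephron development (3.21 against 2.45 to 2.58), glycolysis (5.25 against 4.71 to 4.86) and claudin genes (3.65 against 3.08 to 3.14), and low for proximal tubule markers (7.62 against 7.96 to 8.01). The Il33 transcripts ENSMUST00000025724.8 and ENSMUST00000120388.8 held 25.0% and 75.0% of the gene in Sham 4 and 0 and 100% in the other sham libraries.

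Other libraries stood apart in single values. Cyp1b1 was low in UUO 5 at 14.4 FPKM (23.0 to 24.3 in the other UUO libraries) and mt-Atp6 in UUO 2 at 412 (603 to 684). Intercalated cell markers averaged 3.46 in Sham 5 (3.73 to 3.82 in the other sham libraries) and podocyte markers 1.94 in Sham 3 (1.63 to 1.69). In UUO 4 the Gucy1a3 transcripts ENSMUST00000048976.7 and ENSMUST00000193924.5 held 99.1% and 0.944%, against 99.9% and 0.0508% to 0.0761% in the other UUO libraries. The Reps2 transcript ENSMUST00000112334.7 held 2.84% in Sham 2 (0 in the other sham libraries) and 13.8% in UUO 2 (99.7% to 100% in the other UUO libraries). Nfya-201 held 82.5% in Sham 3 (0 to 0.826% in the others). 2900026A02Rik-202 held 59.4% in Sham 5 (99.7% to 100% in the others), and 2900026A02Rik-203 held 40.6% in Sham 5 (0 to 0.264%) and 41.2% in UUO 5 (81.0% to 93.1%).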

How the results depend on the processing

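All alternatives here were planned except leaving out each library with the tested genes kept, which was chosen after seeing the data, and 91 named genes and 39 lists were recomputed under each that applied; list values are mean log2 differences relative to all other genes, or for fry the lists' own means. All 91 genes kept their direction and side of the threshold with both pseudocounts, both filters and robust eBayes, 85 did in the rank-sum test, 84 with median-of-ratios, 84 with quantile scaling, 87 with equal sums, 88 with sample weights, and 79 to 89 without 1 library (8 genes fell below the filter without a UUO library). Genes at least doubled numbered 3764 and 3896 with pseudocounts of 0.1 and 0.01, since a smaller pseudocount adds to the differences of low genes. After rescaling to equal sums 4235 were doubled, 8884 higher and 1553 lower, with a median of 0.65; this changed both the scale against the pseudocount and the libraries against each other, which were not told apart. Median-of-ratios gave 4506 genes higher, 4522 lower, 1530 doubled and 1346 halved, and 4524 transcripts higher and 4346 lower, and quantile normalization 3908, 4825, 1317 and 1097 genes, by construction, since both remove the shift of the median gene. Sall1, at 0.37 as deposited, lay below the median gene at 0.40 and turned to -0.10 with median-of-ratios, which removes that shift. mt-Co1 turned to 0.12 under quantile normalization, the cause of which was not tested. Leaving out single libraries gave 6536 to 7980 genes higher and 1959 to 2153 lower, 13 to 15 lists higher and 14 to 15 lower, and 71 to 156 changed shares. Without a UUO library the filter, still at 5 libraries, dropped genes low in all sham libraries and left 12279 to 12305 tested, so those counts (6536 to 6819 higher) changed with both. With the 13202 tested genes kept, leaving out single libraries gave 7343 to 8011 genes higher (7435 to 7706 without a UUO library) and 1987 to 2162 lower, 15 to 17 lists higher and 14 to 15 lower, and 87 to 89 of the named genes kept their direction and side of the threshold. Shares changed in 182 transcripts when untransformed. Replicate numbers did not pair the libraries (correlation of residuals -0.26 to 0.15 for equal numbers, -0.25 to 0.27 for others), and the replicate block, which costs degrees of freedom, left 3 changed shares, called the urothelium markers (2.35) and keratin family (2.37) and ended calls of Sall1 and Krt10. In limma with that block the share calls of both Il33 transcripts (adjusted p = 0.0652 and 0.0546), 2900026A02Rik-202 (adjusted p = 0.182), 2900026A02Rik-203 (adjusted p = 0.253), Nfya-201 (adjusted p = 0.217) and ENSMUST00000112334.7 (adjusted p = 0.225) ended. The TGF-beta and BMP signalling list ranged from 0.61 to 0.95, the T and NK cell markers from 0.62 to 0.74, the keratin family from 2.15 to 2.53 and histone genes from -0.23 to -0.15 without 1 library. With the tested genes kept they ranged from 0.87 to 0.95, 0.64 to 0.81, 2.28 to 2.54 and -0.23 to -0.17, and neutrophil markers from 2.01 to 2.73. The TGF-beta list then kept its call without each library and the T and NK list without each but Sham 4 (0.71; limma camera, adjusted p = 0.0629), the keratin family was called without Sham 2 (2.28), Sham 3 (2.30), Sham 4 (2.54), UUO 1 (2.50) and UUO 3 (2.42), and neutrophil markers were called without UUO 3 (adjusted p = 0.0455) and histone genes without Sham 3 (adjusted p = 0.0483). Without a filter and after rescaling to equal sums histone genes were called lower (-0.23 and -0.25), and T and NK cell markers lost their call with the filter at 1 FPKM (0.95). Without UUO 1 limma's camera called histone genes lower (-0.21, adjusted p = 0.0428) and the keratin family higher (2.34, adjusted p = 0.0478), and without Sham 4 the keratin family (2.53, adjusted p = 0.0169). Median-of-ratios called podocyte markers (0.44), neutrophil markers (2.63), urothelium markers (2.42) and the keratin family (2.40) and ended the call of renin-angiotensin and endocrine genes (-0.75). None of the lists it newly called passed with an estimated correlation as well (limma camera, adjusted p between 0.254 and 0.403). Quantile normalization left 8 lists lower: it called neutrophil markers (2.40), cell-cycle arrest and senescence (0.77), urothelium markers (2.34), the keratin family (2.47) and the claudin family (0.99), and ended the calls of principal cell markers (-1.11), glycolysis (-0.12), renin-angiotensin and endocrine genes (-0.45), red blood cell markers (-1.001), the cytochrome P450 family (-0.79) and mitochondrially encoded genes (-0.36). The keratin family was also called with sample weights (2.51) and by camera on ranks (2.37). For these list changes the cause was not tested. With an estimated correlation limma's camera called 0 lists higher and 0 lower (1 and 5 at an unadjusted p under 0.05), since the estimated correlation widens each list's error while its difference stays. The lists that lost their call were the extracellular matrix (3.06), fibroblast, myofibroblast and pericyte markers (1.72), proximal tubule markers (-2.33), thick ascending limb markers (-1.57), distal convoluted and connecting tubule markers (-1.70), principal cell markers (-1.24), intercalated cell markers (-1.24), macrophage and monocyte markers (2.93), T and NK cell markers (0.73), tubular injury markers (3.14), chemokines and cytokines (2.48), TGF-beta and BMP signalling (0.91), complement (2.10), interferon response (1.40), regulated cell death (0.88), proliferation (1.14), fatty acid oxidation (-1.60), oxidative phosphorylation and TCA cycle (-1.39), glycolysis (-0.41), gluconeogenesis (-2.19), renin-angiotensin and endocrine genes (-0.68), red blood cell markers (-1.34), solute carrier family (-0.75), cytochrome P450 family (-0.92), collagen family (1.75), matrix metalloproteinase family (2.16), ADAMTS family (1.04), cytosolic ribosomal proteins (0.51) and mitochondrially encoded genes (-1.63). By fry, which asks about a list's genes alone, 25 lists were higher, among them podocyte markers (0.81), endothelial markers (0.68), B and plasma cell markers (0.86), neutrophil markers (2.92), cell-cycle arrest and senescence (1.02), urothelium markers (2.77), the keratin family (2.79) and the claudin family (1.27). It ended the calls of renin-angiotensin and endocrine genes (-0.25) and the cytochrome P450 family (-0.49, with adjusted p = 0.749 by limma's fry). It called higher nephron development (0.54) and histone genes (0.22), which camera had placed lower without a call. Relative to all other genes, with which fry makes no comparison, the histone mean was -0.20. For nephron development that relative mean was 0.11, and the cause of its disagreement was not tested. Robust eBayes and the rank-sum test give no list results, and the count tools were not run since the tables hold no counts. Depth is unknown, so genes listed at 0 carry no bound.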

Other observations

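The families by symbol root, the tests of the share of the 20 most abundant genes and of proximal tubule RNA, and the later choices of abundant genes were chosen only after results were seen.

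Families of genes that share the root of their symbol were counted among the doubled and halved genes (hypergeometric test, 229 families of at least 8 tested genes, adjusted over 458 tests). A root can also hold genes outside the family it is named for. The hypergeometric test treats genes as independent of each other, though members of a family can vary together. Its p-values therefore do not measure the spread between samples. The collagen list, tested by limma's camera with an estimated correlation, had an adjusted p of 0.246. Genes with the root Cd had the smallest p among the doubled, with 40 of 64 (adjusted p = 2.97e-12), among them the endotoxin receptor gene Cd14, from 1.89 ± 1.37 to 62.6 ± 32.01 FPKM (n = 5 each). Genes with the root Col, of which 25 were in the collagen family tested as a list, followed with 20 of 26 (adjusted p = 2.16e-08), the interferon-inducible Ifi genes with 12 of 13 (adjusted p = 1.79e-06; Ifi211 from 0.927 ± 0.119 to 14.2 ± 2.44 FPKM), interleukins and their receptors with 23 of 40, and the Ms4a genes with 9 of 9 (Ms4a6c from 0.581 ± 0.174 to 22.2 ± 8.74). Lectins (Clec, 10 of 16; Clec4a3 from 0.253 ± 0.144 to 14.8 ± 4.204 FPKM), annexins (7 of 10; Anxa3 from 2.27 ± 1.15 to 34.7 ± 4.23), genes with the root Itgb, not all of them beta integrins (7 of 10, but 3 with median-of-ratios scaling; Itgb2 from 0.553 ± 0.158 to 12.1 ± 3.30) and homeobox genes of the Hoxb cluster (6 of 8, but 3 with median-of-ratios scaling; Hoxb3 from 2.61 ± 0.605 to 12.3 ± 2.16) were also over-represented. Genes with the root Rps, which holds kinases besides ribosomal proteins, were doubled in 20 of 43 cases as deposited and in 1 with median-of-ratios scaling. Matrix metalloproteinases (10 of 11), Ccl and Cxcl chemokines (15 of 24 and 8 of 9), guanylate-binding proteins (8 of 9) and keratins (9 of 12) completed the 15 families over-represented among doubled genes.

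Among halved genes 9 families were over-represented, all of enzymes and transporters, among them solute carriers (67 of 275, and 104 with median-of-ratios scaling) and cytochromes P450 (16 of 40). Carboxylesterases were halved in 7 of 9 cases (adjusted p = 2.59e-06), Ces1g from 16.5 ± 10.9 to 0.548 ± 0.519 FPKM (n = 5 each), and aldehyde dehydrogenases in 9 of 19, Aldh6a1 from 186 ± 18.1 to 48.5 ± 20.2. N-acetyltransferases (6 of 13), carbonic anhydrases (5 of 13), aldo-keto reductases (5 of 14), hydroxysteroid dehydrogenases (5 of 14, and 8 with median-of-ratios scaling) and glucuronosyltransferases (5 of 16) followed. Nat8f6 fell from 109 ± 13.2 to 27.8 ± 19.7 FPKM, Car14 from 39.4 ± 8.17 to 7.997 ± 4.996, Akr1c18 from 51.4 ± 13.7 to 3.68 ± 1.95, Hsd3b2 from 46.0 ± 8.03 to 7.68 ± 4.32 and Ugt3a1 from 79.1 ± 13.0 to 9.08 ± 4.24. Several of these families hold close copies, between which shared reads cannot be assigned with certainty.

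The median gene lay 0.40 higher in UUO, and FPKM are parts of a sum, so a smaller share of abundant kidney genes could raise all others. The 20 most abundant sham genes took 31.2% to 32.5% of the values in sham and 11.9% to 18.9% in UUO, but dividing by the sum without them left a median of 0.31, which argues against these genes as the whole cause. Without the most abundant 10% of sham genes (74.7% to 78.9% in sham, 56.7% to 64.2% in UUO) the median was -0.0176, within the bound of 0.1 written beforehand. Choosing the 10% over all libraries or by UUO, both added afterwards, left 0.13 and 0.31, so the choice of genes decides the answer and the question stays open.

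Rises of immune, stromal and injury genes beside falls of tubule genes might follow from a smaller share of proximal tubule RNA alone, which would raise every other cell type alike. The macrophage list's median of 3.25 lay 4.02 above that of 40 distal segment markers, at -0.76, with a spread of 1.73, which argues against that as the whole cause. A larger number of immune cells and a change within cells stay open, since whole tissue does not part them.

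A random labelling of these libraries is argued against as the source of the counts for genes (9857 called, at most 3590 in the other 99 of 100 splits of the libraries), genes changed 2-fold (3162, at most 938), transcripts (9506, at most 20) and transcript shares (105, at most 17), for each of which 1 split, the real one, reached the count. The splits say nothing of any single call. They cannot exclude chance differences between animals, since nothing shows that the libraries came from separate animals. The number of lists called (29, at most 31 in another split) was reached by 7 of the 100 splits, the real one among them. That number therefore does not speak against a random labelling. Camera with the preset correlation can thus call as many lists under a labelling other than the real one, which limits what its list p-values show.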
